A study of Homo sapiens with 8 samples.

How the data were processed

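Total RNA of THP-1 cells was measured on 8 single-colour Illumina bead arrays, 4 untreated and 4 treated with P4N (3 uM, 12 h). Groups and replicate numbers came from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with DNase treatment, and converted to biotinylated cRNA. The authors deposited an average bead signal per probe, a linear intensity that was not normalized, per the file headers. The deposited file also gives a detection p-value per probe and array. The deposited series matrix holds signal intensity on a linear scale; its columns share 1 distribution (medians 96.0 to 96.1) and the same order of probes as the bead signals, so the authors' quantile normalization was read from the values, not stated. The array design, scanner software and genome build were not given in the sources used here, so no coordinates are printed. No slide was named.

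The intensity was background-corrected with limma's nec, which uses the detection p-values, with an offset of 16, then quantile-normalized and set on the log2 scale. Control probes named ERCC (92) were left out after background correction, 0 to 2 of which were detected on an array. Probes with a detection p under 0.05 on at least 4 of the 8 arrays were kept (17897 probes with a symbol), and 967 probes that passed this filter but had no symbol were left out. Accessions of 28588 probes (60.4%) matched the RefSeq gene table of assembly GCF_000001405.40, used only for names and gene types, and 4091 symbols changed. The probe with the highest mean represented each gene, giving 13961 genes. Each run with another normalization or with arrays left out chose this probe anew. With arrays left out, the filter still asked for detection on at least 4 arrays, so some genes were no longer tested. A probe not detected on any array of a group has only a bound there: the fold was then taken against the higher of the probe's own value and the lowest detected value of each array and printed as at least that fold, with no fold where it was under 1. Counts of changed genes use the fitted values.

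The groups were compared with limma (lmFit and eBayes, 4 against 4, Benjamini-Hochberg adjusted p under 0.05). The 36 gene lists were fixed before the data were examined, and the 32 with at least 3 measured genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Genes are named by a rule fixed then: the 14 largest rises and 14 largest falls among genes past the threshold whose groups do not overlap, leaving out provisional symbols (starting LOC, HS., KIAA or FLJ, or holding orf), and up to 4 members of each list with the smallest p; a list with fewer than 6 changed members may have all of them named. Some genes that the rule names are not reported here. Values of list members do not imply a call unless one is stated. Alternatives were: no background correction, normexp without control information, another offset (50), median scaling, cyclic loess, no filter, a strict filter, the mean of probes, eBayes with trend and robust, the series matrix values, the replicate number as a block, other thresholds and leaving out each array. No normalization, scaling to probes detected on all 8 arrays, averaging untreated replicates 1 and 2, values shifted to the median gene of the main setting, the list counts without each array, leaving out untreated replicates 1 and 2 or 3 and 4, and the class of structural RNAs were added after seeing the data.

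The gene-level test was tested on simulated data with the means and spread of the 13961 genes and 200 changed genes. At a log2 change of 0.5, 0 of 50 changed genes were called; at 1, 16 of 50; at 2, 33 of 50; and at 3, 42 of 50, with 9 false calls among 100 calls. For lists, 5 of 5 simulated lists moved by 1 were called and 0 of the others. Noise was drawn for each gene separately with the same spread in both groups, so the simulated data held no correlation between genes. The list result therefore does not show how often camera calls unmoved lists in the real arrays. Only 200 genes were changed, against 8356 called in the real data, so the shares called may differ there. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.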

Results

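THP-1, a human monocytic leukaemia cell line, was profiled on Illumina bead arrays either untreated (4 arrays) or after 12 h with 3 uM of P4N, a compound known here only by that code name (4 arrays). Each array gave an average bead signal and a detection p-value for 47322 probes. The labels do not say whether the 4 arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. Whether the untreated cells received the vehicle was not stated.

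P4N arrays were dimmer than untreated arrays. A mean of 20046 ± 664 probes (SD, n = 4) was detected on the untreated arrays against 13331 ± 2378 (SD, n = 4) on the P4N arrays (exact permutation test over 70 assignments, two-sided p = 0.0286). The 95th percentile of the signal was 1129 ± 107 in untreated and 196 ± 92.1 in P4N arrays (SD, n = 4 each). P4N replicate 1 had 16857 detected probes and the other 3 P4N arrays had 11684 to 12565. Its gene-level correlation, across genes, with the other P4N arrays was 0.875 to 0.881, while the other 3 correlated with each other at 0.932 to 0.935; genes are not independent replicates. Untreated replicates 1 and 2 correlated at 0.996 with 0 of 13961 genes more than 2-fold apart, against 127 to 279 genes in the other untreated pairs. The deposited column names of untreated replicates 1 and 2 have another form than those of 3 and 4, and the same holds for the P4N replicates. What the forms mean is not stated, so taking the 4 arrays of each group as like replicates is an assumption from the titles. A block on this division was not run. Whether untreated replicates 1 and 2 came from 1 RNA cannot be settled from these values, and untreated n would then be 3. Averaged and counted as 1 array, they left 7101 genes past the threshold (8356 with 4 arrays) and 10 gene lists.

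**Figure D1:**
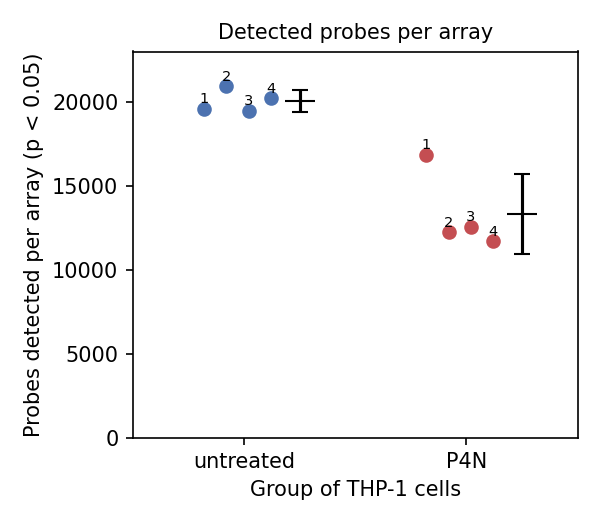
Number of probes detected per array (vertical axis, detection p under 0.05) for untreated and P4N-treated THP-1 cells; points are arrays labelled by replicate, and the bar with whiskers is the mean ± SD of 4. The P4N arrays lie between 11684 and 16857, all below the lowest untreated array at 19467.

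The comparison asked how the transcripts of THP-1 cells differed after 12 h with P4N. In the P4N arrays, all 8 measured metallothionein genes (metal-binding proteins), 13 of 20 genes of cholesterol synthesis and uptake, and stress-response genes such as ATF3, NUPR1 and DDIT3 were higher. Lower were 20 of 22 genes of DNA replication, 24 of 30 cytosolic ribosomal proteins, 11 of 16 endoplasmic reticulum chaperones and 15 of 22 genes of oxidative phosphorylation. These lists passed a test with a preset correlation between genes, each with an adjusted p = 0.826 with an estimated correlation. The ribosomal list turned with cyclic loess (adjusted p = 0.0141). Without normalization its median of -2.73 was that of lists of genes of like brightness (-2.73). Leaving out provisional symbols and taking the brightest probe of each gene, the highest rises were in RNA5S9 (5S ribosomal RNA) by 6.38 ± 0.19 on the log2 scale (± SE, 4 against 4 arrays) and RN7SK (7SK RNA) by 5.96 ± 0.15; another detected probe of RN7SK, less bright, was at 8.28. The largest fall was in FUCA1, a lysosomal fucosidase detected on 1 of the 4 P4N arrays, at -4.30 ± 0.80. All of these values are from quantile-normalized arrays in which the median gene changed by -0.47; without normalization the medians of all 32 tested lists were below 0.

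Of 13961 genes tested, 8356 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 2554 higher and 5802 lower in P4N. At a change of at least 2-fold, 2110 were higher and 3445 lower. The groups did not overlap for 7734 genes (55.4%, where chance gives 2.86%). The split of higher against lower calls depended on the scaling: it was 990 against 11142 with median scaling, 3810 against 2292 with cyclic loess, 826 against 11620 without normalization and 8202 against 1836 when arrays were scaled to the probes detected on all 8 arrays. The median gene moved by -2.02, 0.06, -2.25 and 0.95 in these 4 settings, so the direction of each tested list is also given relative to the median gene. This was done for 3 kinds of normalization: quantile (with 5 background settings), cyclic loess, and 1 factor per array. Median scaling, no normalization and scaling to the probes detected on all 8 arrays are of the last kind and share these values. Bright genes lay lower with that kind. Of genes detected on all 8 arrays, the 3368 brightest in untreated cells had a median change of -3.53 without normalization. The median of all genes was -2.25 there. A list of bright genes may thus lie below the median gene with 1 factor per array whatever its function. Leaving out any 1 untreated array reduced the genes lower to between 3512 and 3638. The filter still asked for detection on 4 arrays, so only 12078 to 12215 genes were then tested. Genes detected on the 4 untreated arrays alone could not pass it. These counts therefore do not separate lost calls from genes no longer tested.

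With quantile normalization, 8 of 8 measured metallothioneins were higher and 0 lower, also when adjusted over the list alone (8 higher). MT1M, detected on 2 of the 4 untreated arrays, changed by 3.47 ± 0.35 (adjusted p = 0.000101), MT1H by 3.07 ± 0.24 and MT1G by 2.74 ± 0.20. The list passed camera with a preset correlation (adjusted p = 1.33e-05; adjusted p = 0.826 with an estimated correlation), and its median lay above the median gene with all 3 kinds of normalization. The adjusted p was 0.000218 without P4N replicate 1, and 0.0533 with median scaling, where the call was lost. The list's own median was 2.12, but -0.37 without normalization and -0.14 with median scaling. List means were 8.34 and 8.40 in untreated replicates 1 and 2, 9.04 and 9.13 in 3 and 4, and 10.7 to 11.1 in the P4N arrays.

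Genes of cholesterol synthesis and uptake were 13 higher and 1 lower of 20 measured (14 and 1 adjusted over the list alone). HSD17B7, a sterol ketoreductase, rose by 3.12 ± 0.13, MVD (mevalonate diphosphate decarboxylase) by 1.98 ± 0.25 and FDPS (farnesyl diphosphate synthase) by 1.63 ± 0.17. The list passed camera (adjusted p = 6.71e-05; adjusted p = 0.826 with an estimated correlation) and lay above the median gene with all 3 kinds of normalization, but did not pass with median scaling (adjusted p = 0.358), without normalization (0.377) or scaled to the probes detected on all 8 arrays (0.183). Its own median was 1.24, but -1.83 without normalization and -1.60 with median scaling. List means were 8.17 and 8.16 in untreated replicates 1 and 2, 7.42 and 7.21 in 3 and 4, and 8.67 to 9.14 in the P4N arrays. Without untreated replicates 3 and 4, 9 members were higher and 0 lower, with a median change of 0.65, and without 1 and 2, 13 were higher and 0 lower, with a median change of 1.60. Without P4N replicate 1, 11 members were higher and 2 lower. The related lists did not pass: fatty acid synthesis had 1 member higher and 3 lower of 8 (FASN at -1.28 ± 0.21), and sterol export had 1 higher and 3 lower of 8, with the sterol transporter ABCG1 at 3.23 ± 0.40 and MYLIP, detected on 1 of the 4 P4N arrays, at -2.68 ± 0.34. Fatty acid synthesis had 1 lower without untreated replicate 1 or 2 and 2 higher without P4N replicate 3. Sterol export had 1 lower without untreated replicate 1 or 2, and 2 higher without untreated replicate 1.

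Of 19 measured targets of ATF4, the transcription factor of the integrated stress response, 10 were higher and 2 lower, also adjusted over the list alone. ATF3 rose by 3.70 ± 0.16, NUPR1 by 3.09 ± 0.25, PPP1R15A by 2.17 ± 0.24 and DDIT3 (CHOP) by 1.79 ± 0.24. The list passed camera (adjusted p = 0.00851; adjusted p = 0.826 with an estimated correlation), and lay above the median gene with quantile normalization and cyclic loess and below it with 1 factor per array; its own median was 0.53, but -2.55 without normalization and -2.32 with median scaling. Members lower numbered 4 without P4N replicate 1, and 1 without P4N replicate 2 or 3 or untreated replicate 1, 2 or 4. Aminoacyl-tRNA synthetases, 4 higher and 3 lower of 12, did not pass (adjusted p = 0.12), with CARS at 2.50 ± 0.17 (another detected probe at 0.79) and IARS1 at -1.12 ± 0.21. With P4N replicate 2, 3 or 4 or any 1 untreated array left out, 2 to 4 synthetases were higher and 1 to 2 lower.

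Endoplasmic reticulum chaperones fell in 11 of 16 members with 0 higher (12 lower adjusted over the list alone; camera adjusted p = 0.0231, 0.109 without P4N replicate 1; adjusted p = 0.826 with an estimated correlation). The list lay below the median gene with all 3 kinds of normalization. Its median without normalization was -3.76, against -3.53 for the 3368 bright genes. PDIA4 was not above background on any P4N array and was at least 1.9-fold lower (adjusted p = 0.000227). MANF changed by -1.17 ± 0.17, DNAJB11 by -0.86 ± 0.14 and HSP90B1 by -1.15 ± 0.19.

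Inflammatory NF-kB targets were higher in 5 of 16 measured members with 0 lower, also adjusted over the list alone (camera adjusted p = 0.0214, 0.109 without P4N replicate 1; adjusted p = 0.826 with an estimated correlation). Without P4N replicate 1, 5 members were higher and 4 lower. The list lay above the median gene with all 3 kinds of normalization, with an own median of 0.43, but -1.45 without normalization and -1.22 with median scaling. BIRC3 rose by 4.25 ± 0.30, although another detected probe of the gene went the opposite way at -0.37. CD83 rose by 1.80 ± 0.24, SOD2 by 1.64 ± 0.24 and NFKBIA, the NF-kB inhibitor, by 1.51 ± 0.22. Among chemokines, a list that did not pass, CCL20 was at 2.80 ± 0.28 and CXCL8 (interleukin 8) at 2.07 ± 0.24.

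DNA replication genes were lower in 20 of 22 members and higher in 0, also adjusted over the list alone (camera adjusted p = 0.00122; adjusted p = 0.826 with an estimated correlation). RFC3 changed by -3.30 ± 0.24 and RRM2 (ribonucleotide reductase) by -2.78 ± 0.27, each detected on 1 of the 4 P4N arrays, and TYMS (thymidylate synthase) by -1.25 ± 0.14. E2F1 was not above background on any P4N array and was at least 1.38-fold lower (adjusted p = 7.47e-05). Mitosis genes were lower in 14 of 24 with 0 higher, also adjusted over the list alone (camera adjusted p = 0.0423; adjusted p = 0.826 with an estimated correlation). TOP2A was at -1.23 ± 0.15, CDK1 at -1.15 ± 0.15 and HMMR at -1.22 ± 0.17. Leaving out any of the 4 P4N arrays ended the call for mitosis, with adjusted p of 0.0638 to 0.118; without P4N replicate 1, 17 members were lower and 1 higher. Both lists lay below the median gene with all 3 kinds of normalization. Without normalization their medians were -3.98 (DNA replication) and -3.57 (mitosis), against -3.53 for the 3368 bright genes.

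Cytosolic ribosomal proteins were lower in 24 of 30 members and higher in 0, also adjusted over the list alone (camera adjusted p = 0.000683; adjusted p = 0.826 with an estimated correlation), as with RPL30 at -1.45 ± 0.16, RPS14 at -1.42 ± 0.16 and RPS6 at -1.30 ± 0.15. The list turned with cyclic loess, where it passed as higher (adjusted p = 0.0141), and lay below the median gene with quantile normalization and with 1 factor per array. Oxidative phosphorylation genes were lower in 15 of 22 with 0 higher (15 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0231, 0.1 without P4N replicate 1 and 0.0526 without replicate 4; adjusted p = 0.826 with an estimated correlation). Without P4N replicate 2, 1 member was higher. The ATP synthase subunits ATP5F1A, ATP5F1B and ATP5PO were at -1.28 ± 0.13, -1.50 ± 0.18 and -0.99 ± 0.12. Myeloid granule genes were lower in 8 of 9 with 0 higher, also adjusted over the list alone (camera adjusted p = 0.0357; adjusted p = 0.826 with an estimated correlation), with SRGN at -1.62 ± 0.13, RNASE3 (detected on 1 of the 4 P4N arrays) at -2.66 ± 0.32 and RNASE2 at -1.41 ± 0.18. That call was lost without P4N replicate 1, 2 or 4 (adjusted p = 0.13, 0.0569 and 0.0526) and with the replicate number as a block (0.0594). Oxidative phosphorylation and granule genes lay below the median gene with all 3 kinds of normalization. Without normalization their medians were -3.43 and -3.22, no lower than the -3.53 of the 3368 bright genes. The own median of granule genes was -0.96, but 0.03 with cyclic loess.

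**Figure D2:**
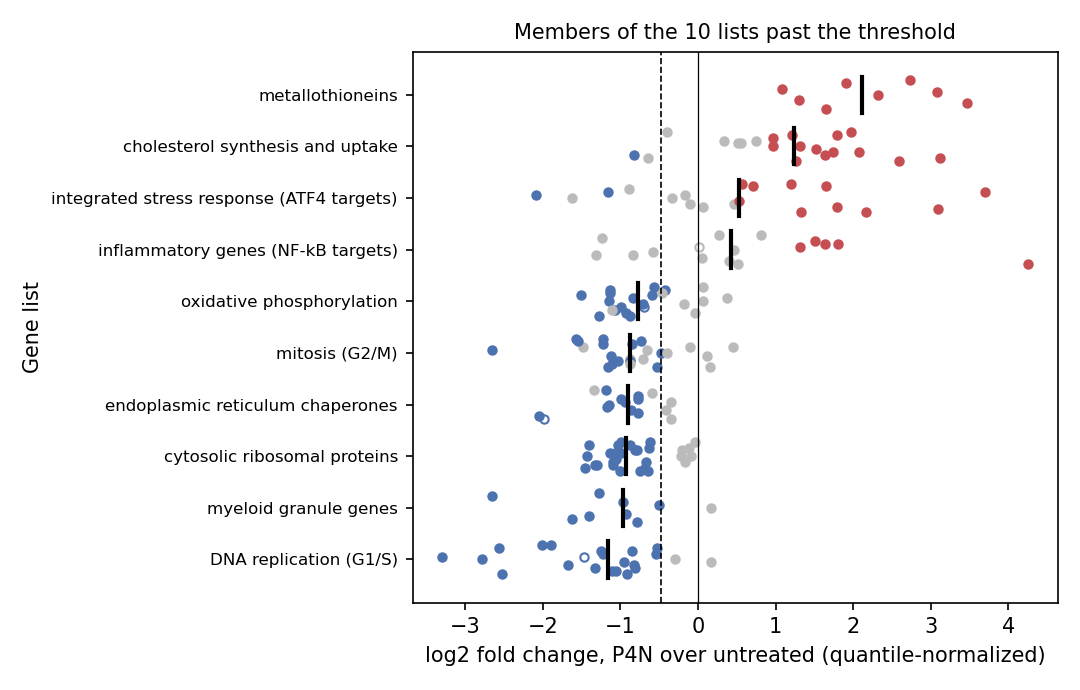
Log2 fold change of P4N over untreated (horizontal axis, quantile-normalized values) for each measured member of the 10 gene lists that passed camera with a preset correlation. Points are genes (red higher and blue lower at an adjusted p under 0.05, grey not past it), thick bars are list medians and the dashed line is the median of all genes at -0.47; open points were not detected on any P4N array and are drawn at fitted values. All 8 metallothioneins are higher here, the medians of all 10 lists were below 0 without normalization, the ribosomal list turned with cyclic loess, and ATF4 targets lay below the median gene with 1 factor per array.

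In all, 10 of 32 tested lists passed, 4 higher and 6 lower. With an estimated correlation between genes, 0 of the 32 passed, each of the 10 having an adjusted p = 0.826 with an estimated correlation, and 1 list had an unadjusted p under 0.05. Without normalization 1 list passed, metallothioneins, and with median scaling 0 passed, with 5 at an unadjusted p under 0.05 (camera). Scaled to the probes detected on all 8 arrays, ATF4 targets (adjusted p = 0.957) and ribosomal proteins (0.641) changed direction. Cyclic loess also ended the calls for oxidative phosphorylation (adjusted p = 0.127) and myeloid granule genes (0.414). Without P4N replicate 1, 5 lists passed: metallothioneins, cholesterol, ATF4 targets, ribosomal proteins and DNA replication. fry, which asks whether members move one way on balance, called 17 lists.

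Untreated replicates 1 and 2 lay apart from 3 and 4 in several lists. Without 1 and 2, 3053 of 9576 tested genes and 10 lists passed, and without 3 and 4, 3256 of 9642 tested genes and 14 lists. NF-kB targets did not pass without 1 and 2 (adjusted p = 0.0799). DNA replication genes were then lower in 7 (without 1 and 2) and 8 (without 3 and 4) of 17, mitosis genes in 9 and 7 of 23, and endoplasmic reticulum chaperones in 5 and 9 of 14. The proteasome list passed as lower in both (adjusted p = 0.0319 and 0.0444). Without 3 and 4, interferon-stimulated genes (6 higher, adjusted p = 0.0106) and chemokines (4 higher, 0.0187) passed as higher and lysosome genes as lower (0.0497), whereas without 1 and 2 these had 0.95, 0.484 and 0.58. Other splits of the 8 arrays gave up to 13 lists, and 6 of the 35 splits gave at least 10. The count of lists thus does not stand apart from other splits. Some of those splits keep most arrays of each group together and so hold part of the P4N difference. They therefore do not measure chance.

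Of the 102 genes named in the text, 84 kept their direction and call without normalization relative to the median gene, 15 lost the call and 3 turned; calls lost there include FDPS, PPP1R15A, DDIT3, CD83, NFKBIA, SOD2, HSPA1A, HSPA1B, RPS6 and E2F1. With median scaling as it stands, 20 of the 102 changed sign.

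Other lists did not pass camera but held members that changed. With all 3 kinds of normalization, the medians of chemokines, interferon-stimulated genes, immediate early genes, histones and B cell markers lay above the median gene. Those of heat shock proteins, lysosome, leukotriene and prostaglandin, BCL2 family, monocyte, MHC class II, NADPH oxidase and ribosome biogenesis genes lay below it. For fatty acid synthesis, sterol export, aminoacyl-tRNA synthetases, NRF2 targets and glycolysis, the median lay above with quantile normalization and cyclic loess and below with 1 factor per array. Autophagy lay above with cyclic loess, and pattern recognition receptors with cyclic loess and 1 factor per array. p53 targets lay above with these and in 3 of 5 quantile settings, and the proteasome in 1 of 5 quantile settings.

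Heat shock proteins were 3 higher and 7 lower of 12: the inducible HSPA1A (2.27 ± 0.18) and HSPA1B (2.03 ± 0.17) were higher, while HSPE1 (-1.32 ± 0.14) and HSPA8 (-0.93 ± 0.14) were lower. Of the NRF2 targets, 3 were higher and 3 lower of 14, with HMOX1, heme oxygenase, at 3.09 ± 0.35 and TXN (thioredoxin) at -1.11 ± 0.14; without untreated replicate 1, 1 was higher and 1 lower, and without untreated replicate 3 or 4, 1 was lower. p53 targets were 4 higher and 4 lower of 13, including ZMAT3 (2.24, with another detected probe at 0.02), TP53INP1 (2.38) and BBC3 (PUMA, 1.99); 1 was lower without untreated replicate 1 or 2, and 2 without untreated replicate 3 or 4 or P4N replicate 2. Among 18 immediate early genes, 5 were higher and 3 lower, with MAFF at 5.35 (another detected probe at 1.69), NR4A2 at 2.52 and MYC at -1.88. Leukotriene and prostaglandin genes were lower in 6 of 12 and higher in 0, with LTC4S (detected on 1 of the 4 P4N arrays) at -2.06 ± 0.24 and ALOX5AP at -1.36 ± 0.21; without P4N replicate 3, 1 was higher. Of 20 monocyte and macrophage markers, 2 were higher and 8 lower, with the Fc receptor FCGR3A at 4.73 and CCR2 (detected on 3 of the 4 P4N arrays) at -2.96; 1 was higher without P4N replicate 2 or 4, and 5 lower without untreated replicate 1 or 2. Of 16 genes of the BCL2 family and apoptosis inhibitors, 3 were higher and 7 lower, with CFLAR at 1.73. With any 1 untreated array left out, 4 of the 13 members still measured were lower. BAD was not above background on any P4N array and was at least 2.26-fold lower (adjusted p = 8.48e-05).

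The proteasome list had 13 of 20 members lower (PSMC4 at -2.13) and 2 higher, with 8 lower without untreated replicate 1 or 4. Ribosome biogenesis had 12 of 18 lower (RRP1B, detected on 1 of the 4 P4N arrays, at -1.80, WDR12 at -1.15) and 1 higher. Lysosome genes were 4 higher and 10 lower of 24 (CTSA at 0.79, changing direction with other scalings), with 6 lower without untreated replicate 1 or 2; HEXA was not above background on any P4N array, and no fold is given. Autophagy genes were 4 higher and 3 lower of 13 (SQSTM1 at 1.25, BECN1 at -1.49), 3 higher and 7 lower without P4N replicate 1, and 2 to 3 higher and 1 to 2 lower with any 1 untreated array left out. Glycolysis and hypoxia genes were 3 higher and 5 lower of 19 (ADM at 2.18, LDHA at -1.17), with 1 higher without P4N replicate 2 or 4 or untreated replicate 1, 2 or 3. Of 19 interferon-stimulated genes, 3 were higher and 0 lower. These were IFI6 (1.59), IRF7 (1.91, another detected probe at 0.40) and IFIT3 (2.12, detected on 3 of the 4 untreated arrays). Another detected probe of IFI6 went the opposite way (-0.13), as did 1 of 2 other detected probes of IFIT3 (median -0.07). Without P4N replicate 4 IFIT3 was at -0.07, near that median. The brightest probe was chosen anew in each run, so this value may come from another probe rather than from the array. Without P4N replicate 1, 3 interferon-stimulated genes were higher and 2 lower, and without untreated replicate 3, 5 were higher. NADPH oxidase genes were lower in 3 of 6 (CYBA at -1.26, RAC2 at -0.96), with 1 higher without untreated replicate 3. MHC class II genes were lower in 1 of 6, HLA-DPA1, which was not above background on any P4N array, so no fold is given. With any 1 untreated array left out, HLA-DPA1 was no longer tested and 4 members were still measured. Of these, 0 were lower without untreated replicate 1, 2 or 4, and 1 without untreated replicate 3. Chemokines were lower in 1 of 10 with 3 higher, and 2 were lower without P4N replicate 1. With any 1 untreated array left out, 8 to 9 chemokines were still measured and 0 were lower. Histones were lower in 2 of 7 with 3 higher. Pattern recognition receptors were lower in 4 of 11 with 1 higher (TLR5, detected on 2 of the 4 untreated arrays, at 2.62), and 2 were lower without untreated replicate 1 or 2. Markers of other cell types were little measured: 1 of 11 for T and NK cells, 3 of 8 for B cells, 2 of 11 for erythroid cells and megakaryocytes, 1 of 10 for fibroblasts and endothelium and 0 of 9 for epithelium.

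Structural RNAs (small nuclear, small nucleolar, ribosomal, Y, vault and related RNAs) were higher in 71 of 136 genes and lower in 1, against 1415 higher and 4972 lower of 10619 protein-coding genes (odds ratio 7.10). Without RNA18SN5 and RNA28SN5, which are not small RNAs, 69 of 134 were higher (odds ratio 6.90). The class was chosen because its members were among the largest rises, so the ratio describes that pattern and does not test it. Besides those named above, RNU6ATAC (detected on 2 of the 4 untreated arrays) was at 5.87 ± 0.14, RNU4-2 (U4 spliceosomal RNA) at 5.50 ± 0.15, RNU11 (detected on 3 of the 4) at 5.45 ± 0.18, RNVU1-7 at 5.44 ± 0.15, SNORD3D at 5.42 ± 0.20 and RNU1-3 at 5.40 ± 0.15. The other genes among the 14 largest rises were TRIM53, ACVR1B, CCDC190, DNHL1, ZNF860 (5.48) and ANKRD44 (5.42). TRIM53, ACVR1B, CCDC190 and DNHL1 were not detected on any untreated array and were at least 44.6-fold, 36.5-fold, 37.6-fold and 35.7-fold higher. Other probes of ACVR1B, TRIM53, DNHL1 and ANKRD44, which did not pass the detection filter, had median changes of 0.04, 0.28, 0.40 and 0.40. CCDC190 and ZNF860 had no other probe. All of these folds are from quantile-normalized values. After FUCA1, whose untreated arrays ranged from 8.20 to 10.97, the largest falls were CACNA2D3 (-3.41), PSME3 (-3.39), RFC3, ALDH1B1 (-3.28), NIP7, NETO2, MRI1, ATP6V0E2, ADCK2, SLC29A1, PIGB, REEP5 and AKAP11 (-3.11). NIP7 and PIGB were detected on 2 of the 4 P4N arrays and each of the others on 1; of the 2 other detected probes of AKAP11, 1 went the opposite way. SLC29A1 was at -1.95 without untreated replicate 3, near its other detected probe (-1.97). The brightest probe was chosen anew in that run, so the value may come from that probe rather than from the array. Other detected probes of RFC3, ALDH1B1, MRI1 and SLC29A1 had median changes nearer 0, at -1.42, -1.86, -1.44 and -1.97. Those of RPS14 (-0.90), RPS6 (-0.85) and LDHA (-0.62) also lay nearer 0 than the brightest probe, and those of CDK1 (-2.17), MYC (-3.51) and WDR12 (-2.23) farther from 0. Of the genes called higher with several detected probes, 286 of 511 had a probe going the opposite way, against 183 of 1482 called lower. Opposite was judged by sign around 0, and the median gene was at -0.47. This favours opposite probes among genes called higher, and no base rate was computed.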

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

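The tests on quantile normalization, on short-lived mRNA, on structural RNA, on genes that rose without normalization and on P4N replicate 1 were chosen only after the result was seen; the other tests were set before. An array was marked when its gap to the nearest array of its group of 4 exceeded Dixon's 95% critical value as a part of the group's range. Of 276 sets of 4 values, 47 were marked, where chance gives about 13.8 (1 in 20), and P4N replicate 1 was the array in 34 of them.

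P4N replicate 1 lay apart in the number of detected probes (gap 0.83 of the range) and in the 95th percentile of the signal (0.859). Among list means it was the highest array for cytosolic ribosomal proteins (0.943), mitosis (G2/M) (0.939), autophagy (0.876), cytosolic aminoacyl-tRNA synthetases (0.856), proteasome (0.856) and oxidative stress response (NRF2 targets) (0.839). Among genes it was the highest P4N array for REEP5 (0.938), RNU1-3 (0.93), SLC29A1 (0.929), ALOX5AP (0.916), TXN (0.915), MRI1 (0.89), AKAP11 (0.875), RRP1B (0.871), ATP6V0E2 (0.87), RRM2 (0.867), FUCA1 (0.865), LTC4S (0.865), PSME3 (0.865), NFKBIA (0.863), RPS6 (0.859) and ADCK2 (0.845). It was the lowest P4N array for MAFF (0.957), BIRC3 (0.951), ZNF860 (0.948), CCDC190 (0.947), FCGR3A (0.939), ANKRD44 (0.934), ABCG1 (0.933), TRIM53 (0.915), DNHL1 (0.884) and RAC2 (0.869). The remaining marked sets were NR4A2 in P4N replicate 3 (0.862), TOP2A in P4N replicate 3 (0.838), RNU6ATAC in P4N replicate 4 (0.897), MAFF in untreated replicate 1 (0.862), RPL30 in untreated replicate 1 (0.839), SQSTM1 in untreated replicate 3 (0.963), E2F1 in untreated replicate 3 (0.916), MYLIP in untreated replicate 3 (0.893), NFKBIA in untreated replicate 3 (0.868), LTC4S in untreated replicate 3 (0.845), CDK1 in untreated replicate 4 (0.985), RAC2 in untreated replicate 4 (0.976) and ribosome biogenesis in untreated replicate 3 (0.933).

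A candidate explanation for P4N replicate 1 is a share of untreated RNA. On the linear scale, structural RNA and other risers then share 1 position, from 0 (untreated mean) to 1 (other P4N arrays). Their medians were 3.68 (33 genes) and 0.705 (793 genes), a difference of 2.97, which argues against 1 mixing share alone. Genes that fell lay at 0.883 (6901 genes). These values were not normalized between arrays, and P4N replicate 1 was brighter (95th percentile 333, against 138 to 165). Mixing beside a difference in brightness therefore stays open. Of the 9340 genes called without P4N replicate 1, 86.0% moved in it with the other P4N arrays, against 46.9% to 51.9% for an untreated array. This argues against an untreated sample under the P4N label. The share lying between the group means was 72.4%, under the 75% set as a bound. A wrong label of another kind therefore cannot be told apart from a different response in that sample by this test. Its mean correlation across genes was 0.877 with the other P4N arrays and 0.864 with the untreated ones. P4N replicate 1 did not respond more weakly throughout. Its normalized means were the highest of the P4N arrays in the 4 lists called higher. They were 9.14 for cholesterol (others 8.67 to 8.96) and 11.1 for metallothioneins (10.7 to 10.9). For ATF4 targets it had 9.24 (8.55 to 8.72) and for NF-kB targets 8.36 (7.13 to 7.41). In each list called lower it was also the highest P4N array, there nearer the untreated arrays. Without P4N replicate 1, 9340 genes passed.

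The large rises may be largely probe-specific signal. For 185 protein-coding genes that rose by 3 or more and have another probe, the other probes had a median change of 0.0658 (quartiles -0.25 to 0.54) where the brightest probe had 3.91, and -0.14 over the 104 genes with another detected probe. The direction of these rises did not depend on quantile normalization, but their size did. Without it the 615 genes had a median change of 1.49 (quartiles 0.95 to 2.23) and 99.3% stayed higher. They were picked by a normalized rise of 3 or more, so a kept direction says little. Of all 2554 genes called higher, 876 were called lower without normalization. A higher share of structural RNA in the P4N samples stays open: that class was picked from the largest rises, so its odds ratio of 7.10 against protein-coding genes restates the pattern and decides nothing.

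Fewer detected probes in P4N arrays could reflect 1 loss of brightness for all genes. Of 5955 genes detected on all 8 arrays, 397 (6.67%, where chance gives 1.43% with no loss) were called higher without normalization with each P4N array above each untreated array (median rise 1.95), and 368 (6.18%) in the signal as deposited, which argues against 1 loss for all genes as the whole cause. Among 3368 bright genes the changes spread 2.91 times as wide as those between untreated arrays, between the bounds of 2 and 3 set in advance; a loss shared by most genes beside changes that differ by gene stays open. A loss of short-lived mRNA after a stop of transcription would leave the mRNAs of ribosomal proteins, as long-lived mRNAs, with more signal. Their median of -2.73 lay at the 48.0 percentile of 10000 lists of like brightness (median -2.73, 95% range -3.03 to -2.35). That is just below the bound of 50 set against this explanation. The verdict also asked for a median below that of the lists by more than their SD, which was not met. The value lies within the lists' spread, so it does not decide. An effect of P4N on RNA content per cell stays open and untested.

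The real split of the 8 arrays called 8356 genes and the highest of the other splits called 0, so 1 of the 35 splits gave as many. That is the smallest share 35 splits can give. Every other split mixes dim P4N arrays with untreated ones, which widens the spread within its groups. The labels also do not say whether the arrays came from separate cultures. The splits thus tie the count to the real grouping but do not exclude chance. For the lists, 6 of the 35 splits gave at least the real count of 10 and the highest other gave 13. Chance cannot be excluded for the number of lists. Splits that keep most arrays of each group together hold part of the P4N difference, so the comparison does not support chance either.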

How the results depend on the processing

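Scalings without normalization, to the probes detected on all 8 arrays, with untreated replicates 1 and 2 averaged, relative to the median gene, list counts without each array and the runs without a pair of untreated arrays were chosen after the data were seen. The number of genes past the threshold stayed within 1.5 times of 8356 except with the strict filter (3277 genes, 4520 tested), a change of at least 2-fold (5555) and without untreated replicates 1 and 2 (3053) or 3 and 4 (3256). Genes higher numbered 990 with median scaling, 1348 with the strict filter, 826 without normalization and 8202 scaled to the probes detected on all 8 arrays. Genes lower numbered 11142, 1929, 11620 and 1836 there, and 2292 with cyclic loess. Leaving out 1 array each left 12078 to 13451 genes tested. It gave 5644 to 9340 genes past the threshold, 2078 to 2438 higher, 3512 to 6902 lower and 5 to 12 lists. Lists past the threshold numbered 0 with median scaling, 1 without normalization, 0 with an estimated correlation and 17 with fry. The cause was not tested, apart from the fewer genes or arrays that the strict filter, the 2-fold limit and the left-out arrays leave.

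The replicate number as a block gave 7519 genes (2387 higher, 5132 lower) and 9 lists, without myeloid granule genes (camera adjusted p = 0.0594). Same-numbered pairs had correlations of -0.041 to 0.018 across genes (the highest 0.0176), so these values show no pairing by number. That highest correlation was 0.0475 with cyclic loess and 0.0752 with median scaling. Averaging untreated replicates 1 and 2 left 7101 genes and 10 lists. A slide block was not run, since no slide is named.

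Of 102 named genes, 102 kept direction and call without background correction, with normexp, an offset of 50, no filter, trend and robust, the series matrix and the replicate block. With median scaling these changed sign (log2 change): FDPS -1.37, MVD -0.31, PPP1R15A -0.65, DDIT3 -1.14, CD83 -1.13, NFKBIA -0.73, SOD2 -1.18, HSPA1A -0.69, HSPA1B -0.84, CCL20 -0.066, CXCL8 -0.11, BBC3 -0.59, CTSA -2.15, SQSTM1 -0.64, ADM -0.36, IFI6 -0.91, IRF7 -0.76, IFIT3 -1.43, CARS -0.44 and CFLAR -1.28. With cyclic loess they were RPL30 0.24, RPS14 0.064, RPS6 0.54 and SRGN 0.12, and relative to the median gene RPS6 0.0091. Relative to the median gene, median scaling, no normalization and scaling to the probes detected on all 8 arrays, which then share their values, turned HEXA 0.37, CTSA -0.59 and HLA-DPA1 0.44. IFIT3 turned without P4N replicate 4 (-0.073, highest without an array 2.62). That value lies near the median of its other detected probes. Each run chose the brightest probe anew, so a change of probe may account for it. E2F1, PDIA4, BAD, HEXA and HLA-DPA1 were not detected on any P4N array, so their values here are fitted values, not measured changes. In 62 other cases a gene kept its direction and lost its call. For lists, ATF4 targets turned when scaled to the probes detected on all 8 arrays (adjusted p = 0.957), and ribosomal proteins turned with cyclic loess (0.0141) and with that scaling (0.641). In 44 other cases a list lost its call, in 29 it gained one, and in 56 a list past no threshold changed direction. The cause of these changes was not tested. The low signal of the P4N arrays over background limits all of these values.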

Other observations

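Genes with symbols starting with LOC, mostly provisional gene models, were higher in 809 and lower in 645 of 2427 tested, with a median change of 0.21 against -0.61 for protein-coding genes (odds ratio for the share higher 3.25; this class was chosen after the data were seen, so no test is given). For 162 protein-coding genes that fell by 2 or more and have another detected probe, the other probes had a median change of -1.22, and in 101 of them the mean of the other probes was lower by over 1; among the 104 genes with a rise of 3 or more and another detected probe, that mean was over 1 in 35.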
